A study of Homo sapiens with 9 samples.

How the data were processed

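Total RNA of 9 samples of HCT-116 cells, 3 per group, had been extracted with Trizol and made into Illumina libraries, per the labels. Genome builds GRCh38 and hg38 are named in the submitters' processing notes. The aligner, the counting tool, the annotation release and the strand setting are not given in the sources used here. Groups and replicate numbers were taken from the sample labels.

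The deposited gene tables, 1 for ORF with NC and 1 for MT with NC, hold a normalized signal per library: in each column every value is a whole multiple of 1 step, so the values are read counts divided by a size factor, set separately in each table. The authors' fold changes in these tables are log2 values. The authors' p-value columns hold a p and an adjusted p per gene or event, and their test is not given in the sources used here. The deposited splicing tables hold other units: reads of the inclusion and the skipping form, inclusion levels from 0 to 1, their differences and the effective lengths of the forms, for skipped exons, retained introns, alternative 3' and 5' splice sites and mutually exclusive exons. Their column layout is that of rMATS, but no source used here names the tool.

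Whole reads per gene were recovered by dividing each column by its step; 100% of values lay within 0.1 of a whole number. The tables hold 31088 genes for MT with NC and 30973 genes for ORF with NC, and the NC reads of all 29612 shared genes were identical. Symbols that a spreadsheet had turned into dates (25 and 26) were replaced through their gene IDs from GENCODE 29, which holds all IDs of both tables. No 2 library columns held identical reads. Recovered totals of 19.5 to 24.4 M reads per library put the floor for a gene without reads, 3 counts over a group, at 0.0464 reads per M reads (CPM) in NC, 0.0488 in ORF and 0.0444 in MT.

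The test fixed before the data were examined was edgeR on read counts, with a fallback for normalized values. As the tables hold normalized values, the fallback was used: limma 3.58.1 in R 4.3.3, eBayes with trend on log2(value + 1), genes at 1 or more in at least 3 libraries, Benjamini-Hochberg adjustment over all genes tested, threshold 0.05. ORF with NC and MT with NC were each tested within their own table. ORF with MT was tested on recovered reads divided by 1 set of median-of-ratios size factors over all 9 libraries. The comparisons, the gene lists, the rule for named genes and most alternatives were also fixed before the data were examined. Simulated data with 200 changed genes, 100 at 2-fold and 100 at 4-fold, were used to check the test. It recovered 80 and 100 in ORF with NC, 96 and 100 in MT with NC, and 86 and 99 in ORF with MT, with 8, 10 and 10 false calls. In the same order the simulated data held 18663, 19052 and 19693 genes, fewer than were tested. How many changes would be recovered among all tested genes is not known.

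In 44791 of 95054 events of the ORF table and 41463 of 88104 events of the MT table, commas between the reads of the 3 libraries had been lost in at least 1 cell. The reads were recovered by finding the split whose inclusion levels matched the deposited levels within 0.001. This gave reads for 81.88% of the ORF events and 82.72% of the MT events, and 17222 and 15222 events were left out, most of them skipped exons with more than 1 matching split. Where 1 form had no reads in a group, the levels could not tell splits apart. Events with many reads and a level of 0 or 1 in a group were therefore prone to be left out. Events needed a mean of 20 reads in each group and an overall inclusion level between 0.05 and 0.95. The log2 odds of inclusion, with a pseudocount of 0.5 and scaled by the effective lengths, were tested with limma, with adjustment within each of the 5 event types. An event was called changed at an adjusted p below 0.05 and an inclusion level difference of at least 0.05. Simulated changes of 2 and 4 in log2 odds, 100 each, were recovered in 69 and 95 events for ORF with NC, 63 and 84 for MT with NC, and 78 and 93 for ORF with MT, with 8, 9 and 8 false calls. These changes were placed only in events with more reads and less extreme levels than the filter required, with 1 fixed spread. Recovery among all tested events is therefore not known.

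Gene lists were tested with limma's camera with a preset inter-gene correlation of 0.01, adjusted over 27 lists: SR proteins and their kinases, hnRNPs and other splicing regulators, core spliceosome, m6A writers, erasers and readers, MYC targets, Wnt/beta-catenin targets, p53 targets, S phase and DNA replication, mitosis, unfolded protein and integrated stress response, interferon response, NF-kB and inflammatory genes, immediate early genes, MAPK output, hypoxia and glycolysis, cholesterol synthesis, epithelial adhesion, mesenchymal and EMT, intestinal differentiation, fibroblast, blood cell, hepatocyte and other cultured epithelial line markers, replication-dependent histones, mitochondrially encoded mRNAs, ribosomal proteins, and cancer isoform genes. Of 26 histone symbols 14 were matched in the tables. A list of small nucleolar RNA host genes was added after the data were seen.

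The named genes are LINC00266-1, MYC and IGF2BP1 in every group. For each comparison they are also the 8 highest and 8 lowest log2 fold changes among called genes with a mean of at least 1 in the higher group and no overlap between groups. Each list adds up to 2 called members per direction by smallest p or, where none was called, its most abundant member. For splicing, the rule takes the 4 highest and 4 lowest differences for skipped exons and 2 and 2 for each other type, 1 event per gene. It adds called events in the SR protein, m6A and cancer isoform lists, up to 4 per list. PKM was followed in every group after its values were seen. Values of 2 genes that the rule names are not reported here.

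The alternatives were edgeR 4.0.16 (TMM or RLE scaling, with and without a filter, 6 or 9 libraries), DESeq2 1.42.0, other pseudocounts, no filter, quantile normalization, a replicate block and leaving out each library. For splicing they were other read minimums, difference minimums and pseudocounts, a quasi-binomial model, the FDR of the deposited table and leaving out each library. For lists they were an estimated correlation, a block and fry. The edgeR run in its originally planned form, an adjustment for GC content and transcript length, limma on 9 libraries, and the run without ORF replicate 1 and MT replicate 2 were chosen after the data were seen. Tables were read and figures drawn with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9.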

Results

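RNA was sequenced from HCT-116, an established human colon cancer cell line, in 3 groups of 3 libraries. The NC group carried an empty vector. The ORF group stably expressed the open reading frame of LINC00266-1, a long intergenic RNA gene whose reading frame encodes a peptide. The libraries labelled MT came from cells described as carrying a construct with this reading frame behind its 5' UTR, with the start codon changed so that no peptide can be made. The series title names messenger RNA splicing as its subject. Gene-level and splicing tables were deposited for ORF against NC and for MT against NC. Recovered reads per library ranged from 19.5 M (mega) reads in ORF replicate 2 to 24.4 M in MT replicate 2. The 3 NC libraries held 20.4, 23.4 and 20.8 M reads, the ORF libraries 22.3, 19.5 and 19.7 M, and the libraries labelled MT 20.4, 24.4 and 22.8 M. No source used here says whether the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. Intervals and detection floors cover counting error only.

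LINC00266-1 (ENSG00000149656, GRCh38 chromosome 20, 64290385 to 64313132) was abundant in ORF and nearly absent in both other groups. It held 9951, 10229 and 10310 reads in the 3 ORF libraries, which is 496 CPM (reads per M reads) over the group (95% Poisson interval 490 to 502). NC held 1 read in total (0.0155 CPM, interval 0.000392 to 0.0862), and the libraries labelled MT also held 1 read (0.0148 CPM, interval 0.000375 to 0.0824). The CPM in ORF were 32100 times those in NC (95% counting interval 5750 to 1270000) and 33500 times those in the libraries labelled MT (interval 6020 to 1320000). The level in the libraries labelled MT thus goes against their label, which names a construct built on this gene. Related copies of LINC00266-1 exist elsewhere in the genome, so reads may be shared with them. MYC (ENSG00000136997), a proto-oncogene transcription factor, held 0.0392% ± 0.000602 of reads in NC, 0.0369% ± 0.000618 in ORF and 0.0381% ± 0.00239 in the libraries labelled MT (SD, n = 3). IGF2BP1 (ENSG00000159217), a reader of the RNA mark m6A, held 70, 65 and 71 reads over the same groups. Neither gene passed the limma test in any comparison, and their adjusted p-values in ORF against NC were 0.727 and 0.874. Shares of reads in ORF are lowered by the large share of PKM, given below. On normalized values the log2 fold change of MYC in ORF against NC was 0.1 ± 0.13 (SE, n = 3 per group).

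**Figure D1:**
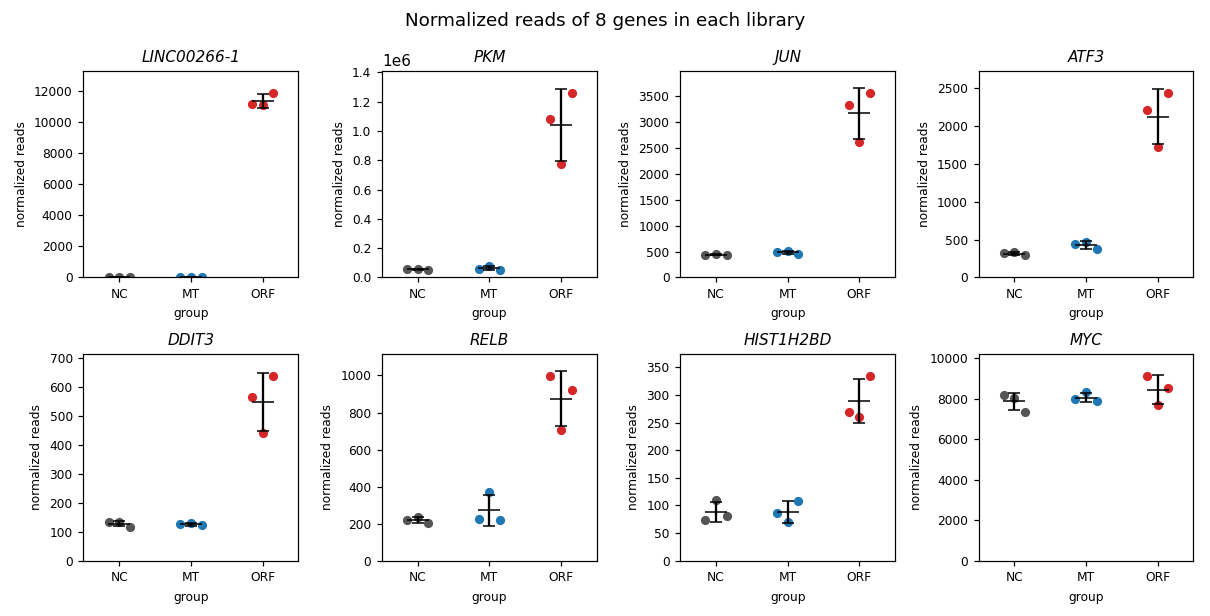
Normalized reads of 8 genes in each library, on linear axes from 0. Points are libraries in replicate order, horizontal marks are group means and bars are SD (n = 3). LINC00266-1, PKM, JUN, ATF3, DDIT3, RELB and HIST1H2BD lay higher in every ORF library than in any other library, while the groups overlapped for MYC.

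The comparison of ORF with NC asks which genes differ when the reading frame is expressed. PKM (ENSG00000067225, chromosome 15, 72199029 to 72231822), the pyruvate kinase of glycolysis, rose 18.7-fold (log2 fold change 4.23 ± 0.21, SE, n = 3 per group; limma adjusted p = 2.8e-06). Its share of all reads was 4.52% ± 0.947 in ORF, 0.271% ± 0.00698 in NC and 0.296% ± 0.0418 in the libraries labelled MT (SD, n = 3). Immediate early genes rose with it: JUN, a subunit of the transcription factor AP-1, rose 7.13-fold and EGR1, a zinc finger transcription factor, rose 6.42-fold. Stress response genes rose too, with ATF3 up 6.63-fold and DDIT3, which encodes the transcription factor CHOP, up 4.2-fold. So did RELB, an NF-kB subunit (3.91-fold), and CXCL8, the chemokine interleukin-8 (7.22-fold). All 6 of these genes were higher in 3 of 3 ORF libraries than in any NC library. LINC00266-1 and PKM were both far higher in ORF than in both other groups. Other changes in ORF, in genes and in splicing, therefore cannot be assigned to the reading frame apart from PKM. Fold changes here and below are on the scale of log2(value + 1), which understates changes of genes with few reads.

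By list, 8 of 22 measured immediate early genes rose and 14 did not pass the test, and 15 rose when adjusted over the list alone. JUN changed by 2.83 ± 0.14 and EGR1 by 2.68 ± 0.14 on the log2 scale (SE; limma adjusted p = 2.8e-06 and 2.86e-06). Of 32 genes of the unfolded protein and integrated stress response, 6 rose and 26 did not pass, and 18 rose when adjusted over the list alone. ATF3 changed by 2.73 ± 0.15 (adjusted p = 4.96e-06) and DDIT3 by 2.07 ± 0.17 (adjusted p = 0.000204). Of 22 NF-kB and inflammatory genes, 4 rose and 18 did not pass, with 9 up when adjusted over the list alone. RELB changed by 1.97 ± 0.16 (adjusted p = 0.000171), CXCL8 by 2.85 ± 0.3 (adjusted p = 0.00124), and the cytokine gene TNF was at least 10.2-fold higher in reads per M reads, with 29 reads in ORF and none in NC. Of 14 genes in the list of replication-dependent histones, which also holds the replication-independent linker histone gene H1F0, 3 rose and 11 did not pass, and 11 rose when adjusted over the list alone. HIST1H2BD rose 3.25-fold (adjusted p = 0.0024) and HIST2H2BE 3.28-fold (adjusted p = 0.0178). Histone genes are near-identical, so reads may be divided among them.

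Of 30 p53 target genes, 2 rose: SESN2, which encodes the stress sensor sestrin 2 (2.37-fold), and AEN, an apoptosis-enhancing nuclease (1.89-fold). Adjusted over the list alone, 13 rose. Of 19 genes of MAPK output, 2 rose: HBEGF, a growth factor of the EGF family (2.22-fold), and FOSL1, an AP-1 subunit (2.26-fold). Adjusted over the list alone, 6 rose and 2 fell. Single members rose in 6 further lists. OASL rose among 36 interferon response genes (2.41-fold; 5 up when adjusted over the list alone), and 1 of 25 mesenchymal genes rose (5 up and 2 down). ANPEP, an aminopeptidase of the intestinal brush border, rose among 15 intestinal differentiation genes (6.54-fold; 1 up). CD14, a monocyte surface receptor, rose among 8 measured blood cell markers (4.86-fold, from a mean of 4.86 ± 0.87 to 28 ± 7.42 normalized reads; 3 up). PKM was the member that rose among 33 hypoxia and glycolysis genes (3 up and 1 down when adjusted over the list alone) and among 39 genes with cancer-related isoforms (2 up and 1 down).

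The other 15 lists, with 394 memberships, held 0 genes past the limma test, against 69 at an unadjusted p under 0.05 and 5 called by edgeR. They were cholesterol synthesis, core spliceosome, epithelial adhesion, fibroblast markers, hepatocyte markers, hnRNPs and other splicing regulators, m6A writers, erasers and readers, mitochondrially encoded mRNAs, mitosis, MYC targets, other cultured epithelial line markers, ribosomal proteins, S phase and DNA replication, SR proteins and their kinases, and Wnt/beta-catenin targets. Adjusted over the list alone, 6 of 20 SR protein and kinase genes rose, as did 1 of 39 MYC targets and 1 of 24 cholesterol genes. In the Wnt/beta-catenin list 1 rose and 3 fell, in the fibroblast list 1 rose and 2 fell, and 1 gene of epithelial adhesion fell. The log2 fold change was 0.38 ± 0.12 for the splicing factor SRSF3, 0.28 ± 0.14 for the core spliceosome protein PRPF8, -0.17 ± 0.13 for HNRNPA1 and 0.24 ± 0.13 for HNRNPC, an m6A reader. It was 0.38 ± 0.17 for the mitotic regulator CDC20, 0.03 ± 0.14 for the nucleolar protein NCL and 0.53 ± 0.13 for the cyclin CCND1. It was 0.37 ± 0.2 for the keratin KRT8, -0.08 ± 0.14 for the collagen COL1A1, -0.28 ± 0.29 for SERPINA1 and -0.3 ± 0.15 for PAX8. It was 0.1 ± 0.2 for the mitochondrial gene MT-CO1 (-1.07 with quantile normalization), 0.19 ± 0.2 for the ribosomal protein gene RPS2 and 0.19 ± 0.17 for the replication helicase gene MCM7.

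The other genes with the highest changes were low in reads. LTA, which encodes lymphotoxin alpha, had 88 reads in ORF and 1 in NC, a ratio of 92.5 in reads per M reads (counting interval 16.2 to 3700). TKTL1, a transketolase-like gene, had 38 and 1, a ratio of 40 on the same scale (interval 6.75 to 1620). Over the group, IFNA22P was at least 20.3-fold higher, MOBP at least 14-fold higher and AC098847.1 at least 9.81-fold higher in ORF. IFNA22P and AC098847.1 are pseudogenes, so their reads may come from related genes. Genes that fell were GAL3ST4, a sulfotransferase (log2 fold change -1.6 ± 0.26), LEMD1 (-1.4 ± 0.23), EBF4 (-1.28 ± 0.18), METTL7A (-1.21 ± 0.21), AL365181.2 (-0.96 ± 0.17) and NEURL1B (-0.86 ± 0.14). AC013643.3 was at least 7.29-fold lower in ORF. The antisense gene RAET1E-AS1 fell by 1.49 ± 0.27 but was not called by edgeR (adjusted p = 0.0877), and its reads cannot be told from those of its partner, since the strand setting of the counting is not stated.

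In all, limma called 103 of 24662 genes, 93 higher and 10 lower in ORF, at an adjusted p below 0.05, and 3867 had an unadjusted p under 0.05. Leaving out 1 library moved both the count and the split. Without ORF replicate 1 limma called 840 genes (429 higher and 411 lower), without ORF replicate 2 it called 1494 (840 and 654) and without ORF replicate 3 it called 24, all higher. Without NC replicates 1, 2 and 3 in turn it called 31, 32 and 36, all higher. Under edgeR on the recovered reads of all 9 libraries, 319 genes were called, 216 higher and 103 lower, and 88 were called by both tests. On the 6 compared libraries, the set used for limma, edgeR called 98, 88 higher and 10 lower. Limma on 9 libraries called 225, 173 higher and 52 lower. With RLE scaling on 9 libraries the edgeR split was 213 higher and 75 lower. After adjustment for GC content and transcript length limma gave 1360 higher and 911 lower. The authors' deposited table has 558 genes with an adjusted p below 0.05, 388 higher and 170 lower, and 91 of these are among the 103. By camera 16 of 27 lists passed with a preset correlation and 0 of 27 with an estimated correlation. Among the 16 were immediate early genes (median log2 fold change 0.7, adjusted p = 1.21e-19), the stress response (0.49, 2.34e-18), histones (1.16, 5.03e-13), NF-kB genes (0.36, 2.85e-08), p53 targets (0.37, 8.59e-08) and MYC targets (0.29, 3.11e-07). The others that passed upward were SR proteins and their kinases (0.22), core spliceosome (0.18), S phase and DNA replication (0.12), interferon response (0.01) and blood cell markers (0.55), and those downward were Wnt/beta-catenin targets (-0.2) and mitosis (-0.16). Ribosomal proteins (0.13), mitochondrially encoded mRNAs (0.12) and hypoxia and glycolysis (0.13) also passed upward, but with quantile normalization their medians turned to -0.08, -0.06 and -0.02. With that normalization the SR, core spliceosome, S phase and MYC target medians were 0.12, 0.03, 0.02 and 0.17. The NF-kB median was 0.19 after adjustment for GC content and transcript length, and the blood cell median 1.23 with edgeR, which kept 3 of 8 members. The interferon median was 0.11 with quantile normalization and 0.05 after the GC and length adjustment. The adjusted p with an estimated correlation was 0.0791 for histones, 0.104 for NF-kB genes, 0.108 for immediate early genes and for p53 targets, 0.214 for the stress response, 0.304 for MYC targets, SR proteins, core spliceosome and mitosis, and 0.501 for S phase. It was 0.214 for the interferon, blood cell and Wnt/beta-catenin lists, 0.528 for the mitochondrial and hypoxia lists and 0.609 for ribosomal proteins.

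The other 11 lists did not pass camera with the preset correlation. Their adjusted p-values were 0.064 for cholesterol synthesis, 0.106 for hepatocyte markers, 0.156 for fibroblast markers, 0.178 for MAPK output, 0.188 for hnRNPs, 0.23 for m6A, 0.302 for mesenchymal genes, 0.377 for other cultured epithelial line markers, 0.421 for cancer-related isoforms, 0.801 for epithelial adhesion and 0.879 for intestinal differentiation. The mean and the median differed in sign for epithelial adhesion (-0.04 and 0.08), MAPK output (0.1 and -0.05) and intestinal differentiation (0.03 and -0.1). Within groups, the deviations of single libraries followed the GC content of genes, most in ORF replicate 1 (r across genes 0.752) and MT replicate 2 (0.724). Among the genes named here, PKM, JUN, EGR1, ATF3, DDIT3, RELB, CXCL8 and HIST1H2BD passed without each library in turn. LINC00266-1, LTA, IFNA22P and MOBP passed without each NC library in turn. Without an ORF library they failed the filter on low values and were not tested. The other genes called lost their call without at least 1 of the NC libraries or ORF replicate 3.

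**Figure D2:**
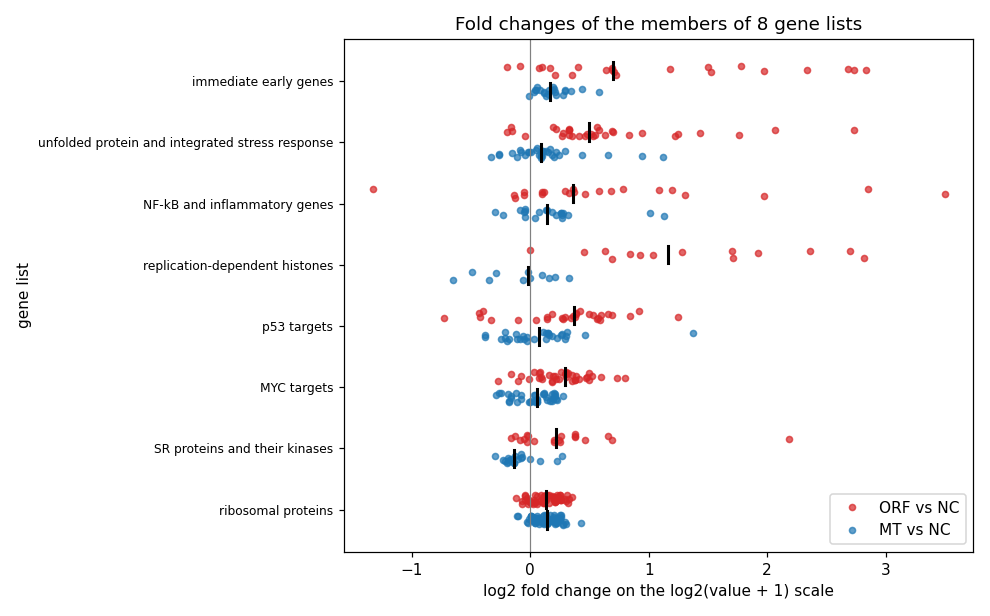
Log2 fold changes of the members of 8 gene lists in ORF against NC and in the libraries labelled MT against NC. Points are genes and black bars are list medians. The median of immediate early genes was 0.7 in ORF and 0.17 in the libraries labelled MT, and that of histones 1.16 and -0.02; the ribosomal median of 0.13 in ORF turned to -0.08 with quantile normalization.

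The comparison of the libraries labelled MT with NC asks which genes differ when the start codon of the reading frame is mutated, but it rests on a label that the LINC00266-1 reads go against. PKM had a log2 fold change of 0.2 ± 0.19 (SE, n = 3 per group; limma adjusted p = 0.761), MYC 0.04 ± 0.11 and IGF2BP1 0.02 ± 0.28. For the most abundant members of other lists the values were 0.32 ± 0.16 for IER3, 0.31 ± 0.15 for the cell cycle inhibitor CDKN1A, 0.36 ± 0.16 for IFITM3, 0.24 ± 0.21 for the glycolytic enzyme ENO1 and 0.26 ± 0.13 for SREBF2. They were 0.32 ± 0.24 for MT-CO1, 0.29 ± 0.12 for COL1A1, 0.43 ± 0.38 for CSF1R, -0.13 ± 0.12 for SRSF3, -0.05 ± 0.13 for HNRNPA2B1, -0.13 ± 0.12 for MKI67 and -0.12 ± 0.13 for HSPD1. For SLC7A5, CD44, CCND1, CDX2, H1F0, MCM7, PRPF8, KRT8, HNRNPA1, PAX8, RPS2 and SERPINA1 they lay between -0.03 and 0.23.

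In the libraries labelled MT, limma called 0 of 25310 genes. The smallest adjusted p was 0.744, and 1183 genes had an unadjusted p under 0.05, against 1266 expected by chance. edgeR also called 0, with 377 at an unadjusted p under 0.05, and DESeq2 called 0. With a replicate block limma called 35 and edgeR 0. The authors' deposited table has 1 gene with an adjusted p below 0.05. Adjusted over the list alone, 2 hypoxia and glycolysis genes, 2 immediate early genes and 3 stress response genes rose and 1 core spliceosome gene fell. By camera 11 of 27 lists passed with a preset correlation and 0 of 27 with an estimated correlation. Medians among the 11 were 0.21 for hypoxia and glycolysis (adjusted p = 2.78e-09), 0.32 for mitochondrially encoded mRNAs (5.35e-06), 0.17 for immediate early genes (0.000188) and 0.14 for ribosomal proteins (0.000188). The other 7 were hnRNPs, S phase, SR proteins, m6A, MAPK output, cholesterol synthesis and the stress response. The SR, hnRNP and stress medians of -0.14, -0.09 and 0.09 turned to 0.03, 0.02 and -0.01 after adjustment for GC content and transcript length, and the immediate early median was then 0.05. With quantile normalization the mitochondrial, ribosomal and hypoxia medians were 0.11, 0.01 and 0.14, and the hnRNP median -0.17. The adjusted p with an estimated correlation was 0.49 for hypoxia and glycolysis.

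The comparison of ORF with the libraries labelled MT was meant to separate the peptide from its RNA, but reads counted at LINC00266-1 were nearly absent in the latter, so every direction here is that of ORF against libraries that go against their label. PKM rose 16.4-fold (log2 fold change 4.03 ± 0.23, SE, n = 3 per group; limma adjusted p = 2.73e-07), JUN 6.45-fold, ATF3 4.91-fold, DDIT3 4.26-fold, CXCL8 8.92-fold and RELB 3.28-fold. SRSF1 and SRSF2, which encode SR proteins that guide exon choice, rose 1.96-fold (0.97 ± 0.15, adjusted p = 0.00594) and 1.45-fold (0.54 ± 0.11, adjusted p = 0.0251). The glycolytic genes ALDOC (-1.07 ± 0.2) and ENO2 (-0.78 ± 0.16) fell, as did DUSP6 (-0.61 ± 0.11) and SPRY4 (-0.48 ± 0.11), which encode feedback inhibitors of MAPK signalling.

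Against the libraries labelled MT, 8 of 22 immediate early genes rose (13 adjusted over the list alone), as did 8 of 32 stress response genes (20), 6 of 14 histone genes (12), 5 of 30 p53 targets (9), 4 of 21 NF-kB genes (6), 3 of 20 SR protein and kinase genes (9 up and 1 down) and 2 of 32 S phase genes (4). Among histones, HIST1H2BD rose 3.28-fold and HIST2H2BE 4.02-fold. The p53 targets PPM1D and SESN2 rose 1.83-fold and 1.96-fold, and the S phase genes RRM2 and GINS3 1.51-fold and 1.63-fold. Of 33 hypoxia and glycolysis genes 1 rose and 2 fell (3 and 8), and of 19 genes of MAPK output 3 rose, among them HBEGF (2.04-fold), FOSL1 (1.97-fold) and CCND1 (1.48-fold), and 2 fell (5 and 4). Of 26 mesenchymal genes 1 rose and the matrix protein gene SPARC fell by 1.49 ± 0.32 (4 up and 2 down). Of 26 epithelial adhesion genes the tight junction gene TJP3 fell by 0.95 ± 0.18 (1 up and 1 down). ODC1, the polyamine enzyme, rose 1.62-fold among 39 MYC targets (1), OASL 2.03-fold among 36 interferon genes (3), ANPEP 5.15-fold among 16 intestinal genes (1) and CD14 4.68-fold among 8 blood cell markers (1). CCND1 was 1 of 18 Wnt/beta-catenin targets that rose (1 up and 10 down) and, with PKM, 1 of 2 among 39 genes with cancer-related isoforms (4 up and 1 down).

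In the other 10 lists, with 262 memberships, limma called 0 genes in this comparison, 35 had an unadjusted p under 0.05 and edgeR called 2. Log2 fold changes were 0.17 ± 0.15 for PRPF8, -0.36 ± 0.13 for COL1A1, -0.47 ± 0.3 for SERPINA1, -0.17 ± 0.13 for HNRNPA1, 0.27 ± 0.13 for HNRNPC, -0.21 ± 0.22 for MT-CO1, 0.21 ± 0.19 for CDC20, -0.36 ± 0.14 for PAX8 and -0.04 ± 0.23 for RPS2. The other genes at the ends of the range had few reads. CASS4, a scaffold protein gene, rose 9.63-fold and FOXQ1, a forkhead transcription factor, fell by 2.38 ± 0.38 on the log2 scale. Ratios of reads per M reads, ORF over the other group, were 48.4 for LTA (counting interval 13 to 406), 22.5 for FAM153A (5.86 to 192), 22 for DRC1 (5.7 to 188) and 20.3 for AC137894.1 (5.25 to 174). In the reverse direction they were 31.8 for TBX18-AS1 (5.35 to 1290), 14.1 for AC008555.2 (3.59 to 122) and 19.1 for OR7D2 (3.07 to 790). KRT18P17 was at least 9.53-fold higher, and AP000696.1, MIR6746 and LINC02097 were at least 7.28-fold, 4.85-fold and 4.24-fold lower in ORF. MTCYBP21 fell by 3.18 ± 0.62. KRT18P17, MTCYBP21, TBX18-AS1 and AC137894.1 are pseudogenes or antisense genes, whose reads may belong to related or overlapping genes.

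In all, limma called 458 of 26546 genes, 239 higher in ORF and 219 lower, and edgeR called 613, 282 higher and 331 lower, with 416 called by both. This limma fit held all 9 libraries. In a fit on the 6 compared libraries, the form used for ORF against NC, limma called 89, 65 higher and 24 lower, and MTCYBP21, AC008555.2, MIR6746, OR7D2, LINC02097, CCND1, TJP3, ALDOC, ENO2, OASL, FOSL1, DUSP6, SPRY4, SPARC, ODC1, SESN2, RRM2, GINS3 and SRSF2 lost their call. By camera 13 of 27 lists passed with the preset correlation and 1 with an estimated correlation, the histones (adjusted p = 0.0418). The 13 were immediate early genes (median log2 fold change 0.59), the stress response (0.45), histones (1.56), NF-kB genes (0.15), p53 targets (0.28), MYC targets (0.27), S phase (0.22), SR proteins (0.35), core spliceosome (0.16), hnRNPs (0.16), m6A (0.12), interferon response (0.08) and, downward, Wnt/beta-catenin targets (-0.37). The histone median was 0.75 with edgeR, which kept 9 of the 14 members, and the NF-kB median 0.32 with edgeR. With quantile normalization the medians were 0.14 for S phase, 0.1 for core spliceosome, 0.06 for hnRNPs and 0.13 for interferon response, and after adjustment for GC content and transcript length that of Wnt/beta-catenin targets was -0.22 and that of interferon response 0.04. The adjusted p with an estimated correlation was 0.051 for immediate early genes, NF-kB genes and p53 targets, 0.0556 for Wnt/beta-catenin targets, 0.115 for the stress response and 0.157 for SR proteins. The mean and the median differed in sign for intestinal differentiation (0.2 and -0.09). Leaving out ORF replicates 1, 2 and 3 in turn gave 1353, 806 and 54 genes, and leaving out MT replicates 1, 2 and 3 gave 72, 137 and 163. Leaving out both libraries that followed GC content most, ORF replicate 1 and MT replicate 2, gave 1507, a choice made after the data were seen. LINC00266-1, PKM, LTA, CASS4, JUN, ATF3, DDIT3, CXCL8, RELB, HBEGF, HIST1H2BD and HIST2H2BE kept their call without each library, while every other called gene named in this comparison lost it without at least 1.

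Across 23763 genes tested in both, the fold changes of ORF and of the libraries labelled MT against the shared NC libraries had a Pearson correlation of 0.394 (Spearman 0.374). Unchanged groups sharing those controls gave 0.5 ± 0.0084 in 100 simulations (SD). The simulation gave all groups 1 spread per gene and drew genes independently, which fixes its correlation near 0.5. The SD of the deviations of single libraries was 0.315, 0.263 and 0.165 in ORF and 0.109, 0.136 and 0.168 in NC. The observed correlation therefore cannot be read as below what shared controls give, and the same limit holds for the covariance. The covariance was 0.0887 against 0.0922 simulated, a difference of -0.0035, and over the 10085 genes with a mean log2 CPM of at least 3 it was 0.0202 against 0.0167, a difference of 0.0035. Genes are not independent replicates, and with 3 controls no split that keeps 2 in each part was possible.

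Splicing was compared between ORF and NC to ask which splice forms differ, the subject of the series title. The 10 retained introns called were all lower in ORF. The retained intron of SNHG12 (ENSG00000197989), a small nucleolar RNA host gene, at chromosome 1, 28579588 to 28579911, fell from a level of 0.821 ± 0.035 in NC to 0.369 ± 0.036 in ORF (SD, n = 3; limma adjusted p = 0.00465). In SRSF3 (ENSG00000112081), an SR protein gene, an exon at chromosome 6, 36599821 to 36600276, annotated only in transcripts marked for nonsense-mediated decay, rose from 0.025 ± 0.003 to 0.103 ± 0.011 (adjusted p = 0.0019). In HNRNPH3 (ENSG00000096746), which encodes an hnRNP, an exon at chromosome 10, 68337858 to 68337996, fell from 0.951 ± 0.014 to 0.767 ± 0.021 (adjusted p = 0.00969).

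Among skipped exons, the largest rise was in CTBP2 (ENSG00000175029), a transcriptional corepressor gene, from 0.776 ± 0.024 to 1. The largest falls were from 1 in NC to 0.356 ± 0.125 in BUD23 (ENSG00000071462), an RNA methyltransferase gene, to 0.497 ± 0.167 in PRMT7 (ENSG00000132600), an arginine methyltransferase gene, and to 0.771 ± 0.078 in AD000671.1 (ENSG00000188223). The intron of the helicase gene DDX11 (ENSG00000013573) at chromosome 12, 31089152 to 31089885, fell from 1 to 0.635 ± 0.134. Alternative 3' splice sites fell from 1 to 0.851 ± 0.028 in RPS18 and to 0.886 ± 0.02 in CYB5R1. Alternative 5' splice sites fell from 1 to 0.565 ± 0.162 in MIB2 and from 0.955 ± 0.01 to 0.804 ± 0.025 in AUP1. A level of exactly 1 means that no library of the group had a read of the other form, so the tested odds there depend on the pseudocount. The events in CTBP2, SRSF3 and SNHG12 kept their call without each library in turn. Those in BUD23, HNRNPH3 and CYB5R1 lost it without ORF value 3, and the other 6 named lost it without at least 1 NC value and 1 ORF value. The quasi-binomial model did not call the events in RPS18 and CYB5R1 (adjusted p = 0.104 and 0.139).

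Of 23233 events tested in ORF against NC, 32 changed (2 higher and 30 lower, in 26 genes) and 2043 had an unadjusted p under 0.05. They were 17 skipped exons (2 higher, 15 lower), 10 retained introns, all lower, 3 alternative 3' splice sites and 2 alternative 5' splice sites, all lower. For mutually exclusive exons limma gave 0 of 9124, with 386 at an unadjusted p under 0.05 and 10 called by a quasi-binomial model. By gene list, 3 changed events lay in ribosomal protein genes, 2 in hnRNPs and other splicing regulators, and 1 each in SR proteins, p53 targets and the stress response. Across all 1566 retained introns 70.1% were lower in ORF, with a median difference of -0.0261. The mean retained intron level per library was 0.354 ± 0.012 in ORF and 0.392 ± 0.017 in NC (SD, n = 3), and each ORF library lay below each NC library. A two-sided exact permutation test gave p = 0.1, the smallest that 3 against 3 allows (0.33 after Benjamini-Hochberg adjustment over 10 such tests). The authors' deposited table gives 5984 events with an FDR below 0.05, of which 2631 were among those tested here with a difference of at least 0.05. Without the ORF values listed as numbers 1, 2 and 3 in the cells, 23 events (10 higher and 13 lower), 27 (9 and 18) and 11 (2 and 9) were called, and a quasi-binomial model called 165, 44 higher and 121 lower.

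**Figure D3:**
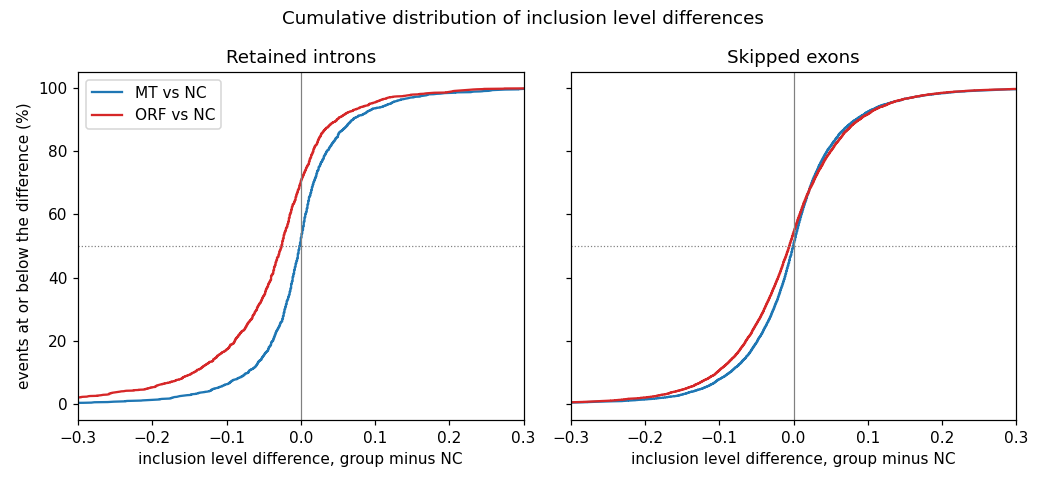
Cumulative distribution of inclusion level differences against NC for retained introns and for skipped exons. The horizontal axis is the difference in inclusion level, and the vertical axis the percent of events at or below it. For retained introns 70.1% of events lay below 0 in ORF and 51.7% in the libraries labelled MT.

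In the libraries labelled MT against NC, 1 of 22094 events changed, and 1055 had an unadjusted p under 0.05. It was a skipped exon of NDE1 (ENSG00000072864), a centrosome protein gene, at chromosome 16, 15699729 to 15699854, which rose from 0.497 ± 0.075 to 1 (SD, n = 3; limma adjusted p = 0.00601). The quasi-binomial model called 4 events. Of 1701 retained introns 51.7% were lower, with a median difference of -0.0014, and their mean level was 0.377 ± 0.019 against 0.378 ± 0.018. A two-sided exact permutation test gave p = 1. The authors' deposited table gives 4507 events with an FDR below 0.05, of which 1792 were among those tested here with a difference of at least 0.05. Without NC value 2 or MT value 3 the NDE1 call ended. Leaving out the NC values 1, 2 and 3 in turn gave 11, 0 and 4 events, and leaving out the MT values 1, 2 and 3 gave 10, 5 and 0.

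Between ORF and the libraries labelled MT, whose label the LINC00266-1 reads go against, the 24 retained introns called were all lower in ORF. SNHG12 had levels of 0.369 ± 0.036 and 0.829 ± 0.016, RBM3, a cold-inducible RNA-binding protein gene, 0.439 ± 0.082 and 0.877 ± 0.032, and TRA2A, a splicing regulator gene, 0.293 ± 0.071 and 0.727 ± 0.111 (SD, n = 3). The SRSF3 exon had levels of 0.103 ± 0.011 and 0.026 ± 0.002. An exon of EIF4A2, a translation initiation helicase gene, rose from 0.135 ± 0.015 to 0.414 ± 0.089, one of OR51B5 from 0.708 ± 0.027 to 0.839 ± 0.022, one of HSCB from 0.862 ± 0.016 to 1 and one of MEF2D from 0 to 0.116 ± 0.067. Exons fell from 1 to 0.455 ± 0.085 in NDE1, to 0.59 ± 0.046 in the RNA-binding protein gene CELF1 and to 0.725 ± 0.069 in TTLL3, and from 0.994 ± 0.011 to 0.771 ± 0.078 in AD000671.1. An alternative 5' splice site of RIOK3 fell from 1 to 0.743 ± 0.015.

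Of 18969 events tested in this comparison, 47 changed, 7 higher and 40 lower in ORF, with 1900 at an unadjusted p under 0.05. They were 22 skipped exons (7 higher, 15 lower), 24 retained introns, all lower, and 1 alternative 5' splice site. For alternative 3' splice sites and mutually exclusive exons limma gave 0, with 143 and 239 at an unadjusted p under 0.05 and 9 and 1 called by the quasi-binomial model. By list, 4 changed events lay in hnRNPs and other splicing regulators, 3 in ribosomal proteins, 3 in the stress response, 2 in SR proteins and 1 in immediate early genes. Of 1551 retained introns 69.2% were lower in ORF (median difference -0.0247). Without ORF value 1 there were 17 events, 10 higher and 7 lower, so the direction of the majority turned. Without ORF value 3 there were 23 (9 higher and 14 lower). Leaving out the MT values 1 and 3 gave 9 and 14, while the quasi-binomial model called 187 but not the TTLL3 event (adjusted p = 0.136). The events in NDE1, SNHG12, RIOK3 and SRSF3 kept their call without each library, and every other event named here lost it without at least 1.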

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

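The tests of LINC00266-1 in the libraries labelled MT, the 2 tests on forms of PKM, the tests on precursor RNA and on nonsense-mediated decay and the gene-level splits were chosen after the results were seen.

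One result lies outside the events tested here. In the authors' deposited table the level of the PKM1 exon of PKM (chromosome 15, 72203022 to 72203188) against the PKM2 exon (72202454 to 72202620) was 0.00367 in ORF and 0.0843 in NC, a difference of -0.081. In the libraries labelled MT the authors' deposited table gives 0.0803, a difference of -0.004. The reads of the ORF cell could not be recovered, so this event was not tested here.

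Reads counted at LINC00266-1 were nearly absent from the libraries labelled MT. If MT cells held LINC00266-1 RNA counted at the gene, a swap with NC libraries needs an NC library with more than 3 reads. The highest NC library held 1, which argues against a swap in that case only. Without such RNA a swap would leave no trace at this gene and stays open. That the cells sequenced as MT carried no expressed LINC00266-1 construct may account for the near absence. It stays open, since the MT level of 0.0148 CPM only restates the pattern. A construct expressed in MT whose RNA is not counted at the gene may also account for it and stays open: limma called 0 genes in MT against NC (1183 at an unadjusted p under 0.05, edgeR 0), which does not decide it. The biological explanation, an effect of the start codon mutation on the RNA, was not tested.

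PKM rose 18.7-fold in ORF, but its forms did not rise alike. The ratios of its minor forms were 0.958 for the longer first exon, 1.09 for the PKM1 exon and 3.91 for the alternative second exon, with a median of 1.09 over these 3, and a further form with the alternative second exon had 3.7, all far below the fold of the gene, which argues against higher transcription of the endogenous gene with unchanged splicing. An intronless PKM copy with the PKM2 exon may account for it: reads of the PKM1 exon were 1092 ± 189 in ORF and 1192.7 ± 141.5 in NC (SD, n = 3), a normalized ratio of 1.09, though the junction from the first to the second exon rose 5.3-fold, which lies between 1.09 and the fold of the gene. Reads shared with pseudogenes stay open: the highest fold was 2.66, below the 4-fold bound set beforehand, but PKMP1 (means 2.55 and 0.295) and PKMP3 (4.69 and 2.38) lie too near the floor for that bound to decide. Higher transcription with a switch towards the PKM2 exon alone would raise the forms at the start of the gene as much as the gene. The longer first exon (0.958), the alternative second exon (3.91 and 3.7) and the first junction (5.3) stayed far below 18.7-fold, which argues against it. A further change of forms at the start of the gene was not tested.

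Of 1566 retained introns 70.1% lay lower in ORF than in NC, and 10 passed the test, all lower, while a two-sided exact permutation test on the mean level per library gave p = 0.1, the smallest that 3 against 3 allows (0.33 after adjustment). The median difference was -0.0373, -0.0235 and -0.0187 in 3 equal groups of events from low to high GC content of the host gene. Its SE was 0.0028, 0.0027 and 0.0025, from resampling introns, which leaves out the spread between libraries. The median thus lay below 0 in every group in these libraries. Whether GC content of the host gene is the whole cause stays open, and GC content of the introns was not tested. Less unspliced precursor RNA may account for the lower retention and stays open. The median log2 odds ratio was -0.35 ± 0.023, -0.34 ± 0.046 and -0.48 ± 0.071 (SE over introns) at levels below 0.2, from 0.2 to 0.5 and of 0.5 or more. The odds fell at every level, as this explanation needs. The fall was not smaller at the highest levels than at the lowest, as it would be with an even share of precursor across introns. That share is not known per intron. A test on inclusion differences, fixed earlier, is void because these are bounded near a level of 0. Reduced nonsense-mediated decay stays open. Its test asked for higher inclusion of exons of decay transcripts, at a permutation p below 0.05, and for a rise of small nucleolar RNA host RNAs. It used skipped exons and no retained introns. The test therefore cannot say in which direction such decay would move intron retention. In it, 649 exons of decay transcripts lay 0.071 above 7063 coding exons in median log2 odds ratio (permutation p = 0.08), which missed the bound. In the libraries labelled MT the difference was 0.015 (permutation p = 0.7). Both permutations shuffled exons, not libraries. The host RNAs were higher in ORF for 14 of 14 members (median log2 fold change 0.45). Their list was chosen after the change of SNHG12 was seen, so this part does not decide it.

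With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real count of genes and the highest of the other splits were 103 and 0 for ORF with NC (1 split as large, the real one included), 0 and 0 for MT with NC (10 splits), and 458 and 0 for ORF with MT (1 split). For splicing events they were 32 and 6 (1 split), 1 and 20 (8 splits), and 47 and 6 (1 split).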

How the results depend on the processing

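The edgeR run on recovered reads, the GC and length adjustment, limma on 9 libraries and the run without ORF replicate 1 and MT replicate 2 were chosen after the data were seen. Genes changed in ORF with NC were 103 by the main test on 6 libraries, 63 with a pseudocount of 0.1 and 210 with quantile normalization. With edgeR they were 319 on 9 libraries, 288 with RLE scaling, 357 without a filter and 98 on 6 libraries. They were 882 with DESeq2, 2271 after GC and length adjustment and 225 with limma on 9 libraries. They ranged from 24 to 1494 when leaving out each library. In ORF with MT, 458 became 199 at 2-fold or more, 78 with edgeR on 6 libraries, 1220 with DESeq2, 3021 after GC and length adjustment, 89 with limma on 6 libraries and 1507 without ORF replicate 1 and MT replicate 2, and ranged from 54 to 1353 when leaving out each library. The cause of these moves was not tested, beyond the fewer libraries of some runs. In MT with NC, every run without a block called 0.

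The replicate numbers do not pair the samples: not every sample correlated best with its own number, and r between libraries of 1 number ran from -0.7 to 0.53. With a replicate block limma gave 301, 35 and 233 genes for ORF with NC, MT with NC and ORF with MT, and edgeR with a block gave 78, 0 and 228. For splicing, no paired analysis was possible because the values carry no replicate number.

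Lists past the test fell from 16 to 0, from 11 to 0 and from 13 to 1 with an estimated correlation in ORF with NC, MT with NC and ORF with MT. In the same order they were 11, 0 and 14 with fry, and 14, 12 and 13 with a replicate block. The correlation of fold changes ranged from 0.403 to 0.507 when leaving out each NC library; no value for unchanged groups was simulated for 2 controls, so these cannot be set against the 0.5 for 3 controls. MT-CO1 in ORF with NC, at 0.1 and not past the test, reversed to -1.07 with quantile normalization and passed the test there.

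Splicing events changed in ORF with NC were 32, and 13 at a difference of 0.2, 165 with the quasi-binomial model and 2631 by the FDR of the authors' deposited table, and ranged from 11 to 33 when leaving out each library. In MT with NC 1 event became 2 at 50 reads, 4 with the quasi-binomial model and 1792 by the FDR of the authors' deposited table, with a range of 0 to 11. In ORF with MT 47 became 16 at a difference of 0.2 and 187 with the quasi-binomial model, with a range of 9 to 38.

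Over all alternatives that tested them, named genes stayed on their side of the threshold in 722 cases for ORF with NC. There 85 lost the call, 12 gained it and 1 reversed past the threshold. The cases were 486 for MT with NC and 828 for ORF with MT (170 lost, 3 gained). These include turns of sign where neither value passed the test. MYC in ORF with NC ran from -0.06 to 0.16. Named events kept their direction and call in 126, 12 and 118 cases and lost the call in 41, 2 and 47. PKM in ORF with NC passed in 18 of 18, from 3.17 to 4.42. Depth limits genes and events with few reads, where 1 read in a control group sets the ratio.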

Other observations

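The list of small nucleolar RNA host genes and the test on nonsense-mediated decay, given above, were chosen after the results were seen.

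Small nucleolar RNA host genes, whose spliced RNAs are by-products of making these RNAs, were higher in ORF than in NC for 14 of 14 measured members. Of these, 3 passed the limma test over all genes: SNHG12 (log2 fold change 0.98 ± 0.15, SE, n = 3 per group; adjusted p = 0.0172), SNHG5 (0.85 ± 0.12, adjusted p = 0.0125) and SNHG15 (0.86 ± 0.16, adjusted p = 0.0413). Adjusted over the list alone, 11 rose. The median was 0.45 in ORF and 0.07 in the libraries labelled MT. As the list was chosen after the splicing change of SNHG12 was seen, its direction is not independent evidence. The list was also 1 part of the test on nonsense-mediated decay.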
